A study of Homo sapiens with 28 samples.

How the data were processed

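C/EBPα ChIP-seq was made in BLaER cells at 0, 12, 24 and 96 h of beta-estradiol and at 1 later time, with 2 libraries per time, beside inputs and ATAC-seq. The treatment labels of the 4 libraries of the later time contradict their titles, and no values of that time were used here. Groups were taken from the sample titles. Per the labels' protocols, cells were fixed with formaldehyde and sheared by sonication, and chromatin was precipitated with an antibody against C/EBPα. Per the submitters' processing notes, the tools included STAR 2.3.0, SAMtools, MACS2, deepTools 2.3.4 and HTSeq, with cutadapt 1.9.1 and Trim Galore 0.4.1 for the later time, on hg38, and the role of each tool is not given in the sources used here.

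The deposited signal values are a table with 1 value per merged C/EBPα peak and time, which the authors scaled in a way not given in the sources used here. A deposited list gives the position and width of each of the 14561 merged peaks (1-based, 24 chromosomes, 0 peaks past the end of an hg38 chromosome) and a TRUE or FALSE under K0 and A0, whose meaning no source states. The numbers of the peaks run to 17650, and 3089 of them are absent from what was used here. Values are pooled per time, never negative and not whole, so no read depth, counting interval or count test could be had. The design fixed before the data were examined had assumed a count table with a count test or, for 1 column per time, values with no test. The second case applied, so the peaks named per comparison follow the rule for values with no test.

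The deposited values were compared by log2(value + 1), a scale that understates the change of low values, and a peak was counted as higher or lower at a change of at least 2-fold. Within each time, values of peaks that start at or past 10 Mb on their chromosome proved to be sums of whole multiples of 2 steps. Such parts were recovered at all 4 times for 13288 of the 13293 peaks past 10 Mb (99.96%) and for 0 of the 1268 peaks below it. The parts were taken as the 2 libraries of a time and are called the smaller-step and larger-step part. This reading comes from the numbers alone, and no label states it. On 4000 simulated values per column made from known steps, 100% were recovered and 0% of values off the steps were given parts. No source states whether the whole numbers count reads or covered bases, and this was not tested, so they were not given a count test.

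log2(part + 1) was tested with limma 3.58.1 in R 4.3.3 (trend and robust variance, time as a factor, all 8 parts in 1 fit) with Benjamini-Hochberg adjustment per comparison. This test was chosen after the data were seen. On simulated data for 12 h against 0 h over 13288 peaks, it found 22% of 100 peaks changed by a log2 of 2 and 79% of 100 changed by a log2 of 4, with 8 false calls. With so few changed peaks the adjustment was stricter than in the real fit, so these shares do not carry over to it. The log2 parts of 1 time correlated across peaks at 0.49, 0.79, 0.72 and 0.55 at 0, 12, 24 and 96 h. Peaks are not independent replicates.

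Peaks were assigned to the nearest protein-coding transcription start of GENCODE 44, at most 100 kb from the midpoint of the peak. This gave a gene to 9490 peaks (65.2%). Named peaks are the 5 largest rises and 5 largest falls per comparison by the deposited values among peaks with a mean signal above the median peak, plus 2 to 4 genes per list with the largest change, by size, at 96 h against 0 h in the gene's strongest peak. The design had named the later time for this ranking, which has no values, and for lists with no call had also allowed the strongest peaks. S100A9, ADIPOQ and IL1B were chosen after their values were seen. CYBB and CD14 were named by both parts of the rule. The 11 gene lists were fixed before the data were examined. They covered myeloid transcription factors, macrophage and monocyte genes, granule genes, inflammatory mediators, phagosome and lysosome genes, lipid and cholesterol handling genes, B cell genes, T cell and NK cell genes, erythroid and megakaryocyte genes, liver and fat cell genes, and cell cycle and housekeeping genes. All 187 list genes were found in the annotation. Lists with at least 3 tested peaks (10 of the 11) were tested with camera in limma at a preset correlation of 0.01, adjusted over 30 list and time pairs.

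Motif matches were searched on both strands of the hg38 sequence in the central 200 bp and in a window of the same width 2 kb to the right, and shares were compared with Fisher's exact test, two-sided, adjusted over 36 motif tests or 7 promoter tests. Wilson intervals are at 95%. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

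Alternatives set before the data were examined were median-of-ratios scaling, scaling to column totals, pseudocounts of 0.1 and 10, a filter on low values (applied as peaks above the median mean signal), a fit of only the times compared, each replicate left out, stricter thresholds, an estimated correlation in camera, a 20 kb distance limit, a 5 kb promoter window and other motif windows. They were planned for libraries and applied to columns or parts. Alternatives added after the data were seen were the test on parts itself, leaving out chromosome 8 or the peaks below 10 Mb, removal of a GC trend from each part by lowess with a span of 0.3, 96 h as the last time of the classes, and list tests after scaling or GC correction. The simulated overlap at the observed list lengths was also added after the results were seen. Left out were the later time, the inputs, the ATAC libraries and any test of the peaks below 10 Mb, which have no parts.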

Results

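BLaER cells are a human B-cell leukaemia line (RCH-ACV) that carries an estradiol-inducible form of C/EBPα, a transcription factor of the myeloid lineage, and that converts from a B-cell-like to a macrophage-like state when 100 nM beta-estradiol is added. The series held 28 libraries. There were 10 C/EBPα ChIP libraries and 10 input libraries, with 2 of each at 0, 12, 24 and 96 h and at 1 later time, and 8 ATAC libraries, with 2 each at 0, 12, 24 and 96 h. The values used here were C/EBPα ChIP signal at 14561 merged peaks on hg38, with 1 deposited value per peak at 0, 12, 24 and 96 h. Values for the later time, for the inputs and for ATAC were not analysed here. The peaks had a median width of 337 bp (range 216 to 9634 bp) and covered 5.61 Mb.

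Each deposited value pools the 2 libraries of its time. For 13288 peaks the value could be split into 2 parts per time, taken here as the 2 libraries, which is an inference from the numbers that no label states. Changes below are given as deposited values and as limma estimates on log2 parts with their standard error (SE, 2 parts per time). The labels do not say that the libraries came from separate cultures. The p-values therefore measure only spread between parts, which may be technical. The fit draws each peak's spread towards a spread shared by peaks of like signal, so an SE is not the spread of its own parts. The peaks assigned to RGS18 and PCBP1 had SEs of 0.62 and 0.61, with 0 h parts of 17.8 and 152.0 and of 198.0 and 161.6. The smallest p-values below rest on that shared spread and not on the 2 parts alone. Sequencing depth is unknown because the values are scaled signal and not read counts.

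C/EBPα signal was higher over the peak set at every time in estradiol than at 0 h, before any rescaling. The merged peak list belongs to this same series, and the sources used here do not say at which times its peaks were called. Sites called only in estradiol would enter the list because their signal is high there. The higher medians, and the few falls against 0 h given below, may thus be set in part by how the list was made. The median deposited value was 1184 at 0 h, 2563 at 12 h, 2075 at 24 h and 1882 at 96 h. Column totals were 2.30e+07, 4.76e+07, 4.26e+07 and 3.85e+07 in the same order. Past 10 Mb, the smaller-step and larger-step parts had medians of 584 and 664 at 0 h and 978 and 1680 at 12 h. Those medians were 884 and 1310 at 24 h and 1076 and 907 at 96 h, so the 2 parts of 1 time also differed. Because the scaling behind the columns is not stated, each comparison is also given after median-of-ratios scaling of the columns or parts, which by construction sets the median change near 0. It removed a median log2 change of 1.02 at 12 h, 0.82 at 24 h and 0.61 at 96 h against 0 h, and of −0.22 from 12 h to 24 h and −0.27 from 24 h to 96 h.

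The first comparison asked which sites gained or lost C/EBPα in the first 12 h of estradiol. The largest gains lay at peaks assigned to RGS18, RFLNB, CD14, CYBB and DHRS9. At the promoter of RGS18, a regulator of G-protein signalling in blood cells, signal went from 169.9 to 8503 (chromosome 1, 192158115 to 192158602), and the limma estimate was 6.28 ± 0.62 (SE, adjusted p = 1.12e-19). A peak 21.4 kb downstream of the start of CD14, which encodes a monocyte co-receptor for lipopolysaccharide, went from 606.2 to 16002 (chromosome 5, 140612023 to 140612574, intergenic) and rose by 4.81 ± 0.55 (SE, adjusted p = 1.07e-14). A peak in an intron, 20.9 kb downstream of the start of CYBB, the catalytic subunit of the phagocyte NADPH oxidase, went from 187.7 to 4969 (chromosome X, 37800657 to 37801117) and rose by 4.84 ± 0.66 (SE, adjusted p = 1.70e-10). A peak in an intron of DHRS9, a retinol dehydrogenase family member, rose by 4.68 ± 0.59 (SE, chromosome 2, 169071983 to 169072815, adjusted p = 6.57e-12). A peak 54.4 kb upstream of RFLNB went from 559.3 to 14903 (chromosome 17, 499964 to 500645, intergenic) and had no parts to test. It starts below 10 Mb, where deposited values lay lower by an amount that differed by time, so its change may be shifted.

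Lower values at 12 h were few. The largest were at peaks assigned to NPIPB5, RHBDF1, an unnamed chromosome 19 gene, PAG1 and PTK2B, with deposited log2 changes of −1.59, −1.29, −1.26, −1.21 and −1.18. PAG1 encodes an adaptor protein of lymphocyte membranes and PTK2B a non-receptor tyrosine kinase. None of the 4 with parts passed limma as deposited (adjusted p from 0.0754 for NPIPB5 to 0.241 for PAG1), while after median-of-ratios scaling their adjusted p lay between 0.00535 and 0.0244.

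Of all 14561 peaks, 7370 were at least 2-fold higher at 12 h and 296 at least 2-fold lower. After median-of-ratios scaling the split was 2192 higher and 2330 lower, and after scaling to column totals 2168 and 2349. By limma 2814 of 13288 peaks rose and 12 fell at an adjusted p under 0.05, against 786 and 304 after median-of-ratios scaling and 790 and 302 after scaling to totals. The rises at RGS18, CD14, CYBB and DHRS9 passed after median-of-ratios scaling too (adjusted p from 1.22e-05 to 0.00145). Without the larger-step 12 h part the rises numbered 523, without the smaller-step 0 h part 1311, and without the larger-step 0 h part 1743, and the falls numbered 0 without either 0 h part.

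The second comparison set 24 h against 0 h. RGS18 stayed high at 8319, a rise of 6.08 ± 0.62 (SE, adjusted p = 2.51e-18), and so did CD14 at 17767, a rise of 4.96 ± 0.55 (SE, adjusted p = 4.79e-16). A peak in an intron, 7.13 kb downstream of the start of ALDH2, the mitochondrial aldehyde dehydrogenase, went from 428.2 to 14897 (chromosome 12, 111773759 to 111774270) and rose by 4.97 ± 0.59 (SE, adjusted p = 1.03e-13). A peak 26.1 kb upstream of PADI4, a peptidylarginine deiminase of neutrophils and monocytes, went from 318.1 to 10312 (chromosome 1, 17281798 to 17282333, intronic by the annotation) and rose by 5.14 ± 0.62 (SE, adjusted p = 1.82e-13). At ADORA2B, an adenosine receptor, the value was 313.0 at 0 h and 9724 at 24 h (chromosome 17, 15927921 to 15928394, intergenic), with an adjusted p of 0.161.

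Falls by 24 h included a peak in an intron 30.1 kb downstream of the start of ZC3H18, an RNA-binding zinc-finger protein, from 17420 to 2876 (chromosome 16, 88600174 to 88600750, −2.59 ± 0.56, SE, adjusted p = 8.62e-05). Signal also fell at peaks near SNED1 (−2.51 ± 0.66, SE, adjusted p = 0.00176) and ROBO2 (−2.23 ± 0.65, SE, adjusted p = 0.00583), the latter an axon-guidance receptor. Peaks assigned to STUM and ZMYND8 fell by 1.86 ± 0.68 and 1.84 ± 0.63 on the log2 scale (SE, adjusted p = 0.0344 and 0.0232). Among all peaks, 6350 were at least 2-fold higher and 610 lower, against 2801 and 2709 after median-of-ratios scaling and 2656 and 2908 after scaling to totals. By limma 2696 rose and 52 fell, against 1332 and 852 after median-of-ratios scaling and 1305 and 897 after scaling to totals. Without the larger-step 24 h part 822 rose, and without either 0 h part 1373 or 1740 rose and 9 or 3 fell. The falls numbered 29 without the smaller-step 24 h part and 106 when only these 2 times were fitted.

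The third comparison set 96 h, the last time with values, against 0 h. Signal at RGS18 reached 12983 (6.90 ± 0.62, SE, adjusted p = 3.15e-24) and at CYBB 8428 (5.57 ± 0.66, SE, adjusted p = 6.04e-14). A peak 43.8 kb upstream of PCBP1, a poly(C)-binding protein, went from 359.6 to 15629 (chromosome 2, 70043366 to 70043900, intergenic) and rose by 5.44 ± 0.61 (SE, adjusted p = 4.06e-15). DHRS9 rose by 4.82 ± 0.59 (SE, adjusted p = 8.91e-13), and a peak 51.2 kb upstream of TMPO, a nuclear-envelope protein gene, by 4.68 ± 0.54 (SE, chromosome 12, 98464073 to 98464625, intergenic, adjusted p = 2.35e-14).

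Sites that lost signal by 96 h included a 17.8-fold fall. This peak, in an exon 13984 bp downstream of the start of HEYL, a transcriptional repressor downstream of Notch, went from 5024 to 281.9 (chromosome 1, 39625415 to 39625904, −4.24 ± 0.66, SE, adjusted p = 2.86e-08). A peak assigned to BMP10 went from 7371 to 433.4 (chromosome 2, 68789453 to 68789941, −4.83 ± 0.66, SE, adjusted p = 1.67e-10). Peaks near ACBD4 and CRB2 fell by 3.58 ± 0.60 and 3.79 ± 0.70 on the log2 scale (SE, adjusted p = 2.27e-07 and 3.40e-06). At C13orf46 the value was 5395 at 0 h and 441.9 at 96 h, with an adjusted p of 0.236. In all, 5397 peaks were at least 2-fold higher and 1401 lower, against 3235 and 2850 after median-of-ratios scaling and 2737 and 3390 after scaling to totals. By limma 2262 rose and 396 fell, against 1554 and 1250 after median-of-ratios scaling and 1341 and 1524 after scaling to totals. The rises numbered 1094 without the smaller-step 96 h part, 1435 without the larger-step 96 h part and 1183 without the smaller-step 0 h part, and the falls 132 or 138 without either 0 h part.

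Between 12 h and 24 h no change at a single peak passed the test. The largest higher values among peaks with parts were at CCR2, a chemokine receptor of monocytes, at 1750 and 7566 (chromosome 3, 46312935 to 46313412, intergenic, adjusted p = 0.279), and at EYA3, TAB2 and GSTK1 (deposited log2 changes of 2.01, 1.98 and 1.93). The largest lower values among these peaks were at MBNL3, a splicing regulator, at 5055 and 886.8 (chromosome X, 132474503 to 132474893, intron, adjusted p = 0.218), and at CSPG5, CDH19 and GOT1 (−2.41, −2.33 and −2.25). Peaks assigned to TUBB8B and THOC1, with deposited log2 changes of 2.81 and −2.97, had no parts to test. Both start below 10 Mb, where changes over time may be shifted. Of all peaks 1395 were at least 2-fold higher at 24 h and 2215 lower, against 1960 and 1425 after median-of-ratios scaling and 1842 and 1553 after scaling to totals. limma called 0 peaks higher and 0 lower, with 926 at an unadjusted p under 0.05, and 1 higher under either scaling. It called 80 lower without the larger-step 24 h part and 2 lower without the smaller-step 24 h part.

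From 24 h to 96 h binding changed in both directions. A peak 40.8 kb downstream of the start of GPR65, a proton-sensing receptor of immune cells, went from 1395 to 15014 (chromosome 14, 88045664 to 88046165, intergenic) and rose by 3.49 ± 0.70 (SE, adjusted p = 0.00018). Signal rose near CLEC9A, a C-type lectin receptor of dendritic cells, from 1521 to 9043 (chromosome 12, 10068674 to 10069020, 2.79 ± 0.68, SE, adjusted p = 0.00341). The ROBO2 peak that fell by 24 h rose by 3.02 ± 0.65 (SE, adjusted p = 0.000726), and peaks near PRTFDC1 and UBXN2B each rose by 2.43 ± 0.68 (SE, adjusted p = 0.0147 and 0.0146). The largest fall was at TFAP2C, a transcription factor of the AP-2 family, from 14213 to 610.1 (chromosome 20, 56658235 to 56658889, intergenic, −5.31 ± 0.63, SE, adjusted p = 8.05e-13). The HEYL peak changed by −3.70 ± 0.66, a peak near CERK by −3.44 ± 0.66 and a peak near CDH3 by −3.32 ± 0.57 (SE, adjusted p = 1.89e-05, 8.27e-05 and 1.19e-05). A peak near CYTL1 had no parts and a deposited log2 change of −3.64.

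Of all peaks 1799 were at least 2-fold higher at 96 h than at 24 h and 3276 lower, against 2432 and 2237 after median-of-ratios scaling and 2112 and 2670 after scaling to totals. By limma 269 rose and 515 fell, against 775 and 718 after median-of-ratios scaling and 663 and 877 after scaling to totals. On chromosome 8, 124 peaks rose, and a fit without that chromosome called 131 rises. The rises numbered 30 without the smaller-step 96 h part, 79 without the larger-step 96 h part and 50 without the smaller-step 24 h part, and the falls 120 without the larger-step 24 h part, 284 without the smaller-step 24 h part and 310 without the larger-step 96 h part. Peaks that fell were richer in G and C (median 50.0%) than peaks that rose (median 37.5%). After a GC trend was removed from each part, 94 rose and 354 fell, and with only these 2 times fitted 518 rose and 434 fell, so which direction was more common depended on the fit.

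Over the 4 times together, 4373 of 13288 peaks changed by limma (adjusted p under 0.05), and 3822 after median-of-ratios scaling. Without the smaller-step 0 h part the number was 2586. Timing classes were made from the calls above, with 96 h as the last time. The early class (higher at 12 h than at 0 h) held 2814 peaks, the CD14, CYBB and RGS18 peaks among them, and the late class (not early, higher at 96 h) held 911. The transient class (higher at 12 h or 24 h and lower at 96 h than at 24 h) held 243, and the lost class (lower at 96 h than at 0 h), with HEYL and BMP10, held 396. A peak can be in more than 1 class, and 9160 of the tested peaks were in none. After median-of-ratios scaling the classes held 786, 1052, 183 and 1250 peaks. Rises at 12 h and at 24 h shared 2057 peaks, where independent lists would share 570.9. In 20 simulations of unchanged groups against the same 0 h parts, the called lists held on average 1.00 and 0.80 peaks and shared 0.25, and lists ranked by p and taken to the observed lengths shared 1227 on average. Rises at 24 h and 96 h shared 1528 peaks (458.9 for independent lists, 0.20 simulated, 1043 at the observed lengths). The 0 h controls were not split, as each side would have kept only 1 part, so much of either overlap may come from the shared controls.

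Macrophage and monocyte genes gained binding as a list at all 3 times. Of their 35 tested peaks, 19 rose at 12 h, 19 at 24 h and 20 at 96 h, and 1 fell at 96 h. Adjusted over the list alone, 22, 21 and 23 rose and 2 fell at 96 h. The median log2 change of the list was 1.81, 2.01 and 1.96 against 0.99, 0.79 and 0.62 for all tested peaks (camera with a preset correlation, adjusted p = 2.58e-06, 6.59e-07 and 2.29e-06). The adjusted p was 0.947 at each time with an estimated correlation, and 0.0581 with an estimated correlation after median-of-ratios scaling. The 0.947 came from unscaled parts, whose levels differed within a time (median-of-ratios factors of 0.993 and 1.71 at 12 h). Such a difference is shared by all peaks and enters the estimated correlation. The 0.947, here and for the lists below, therefore does not measure ties between the peaks of a list alone. That scaling left 7, 13 and 15 rises and 0, 1 and 2 falls in the list. At 39.1 kb upstream of CD163, the haemoglobin scavenger receptor of macrophages, the deposited value went from 90.8 to 495.7, 2472 and 10333 (chromosome 12, 7542799 to 7543177, intergenic), with no parts to test. That peak starts below 10 Mb, where changes over time may be shifted. CD14 was still raised at 96 h (4.11 ± 0.55, SE, adjusted p = 5.80e-11). A peak 10.1 kb upstream of LYZ, the lysozyme gene, rose by 4.47 ± 0.65 at 96 h (SE, chromosome 12, 69338143 to 69338507, adjusted p = 2.80e-09), and the promoter peak of S100A9, a calcium-binding protein of myeloid cells, rose by 3.48 ± 0.56 (SE, chromosome 1, 153357501 to 153358028, adjusted p = 5.80e-08).

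**Figure D1:**
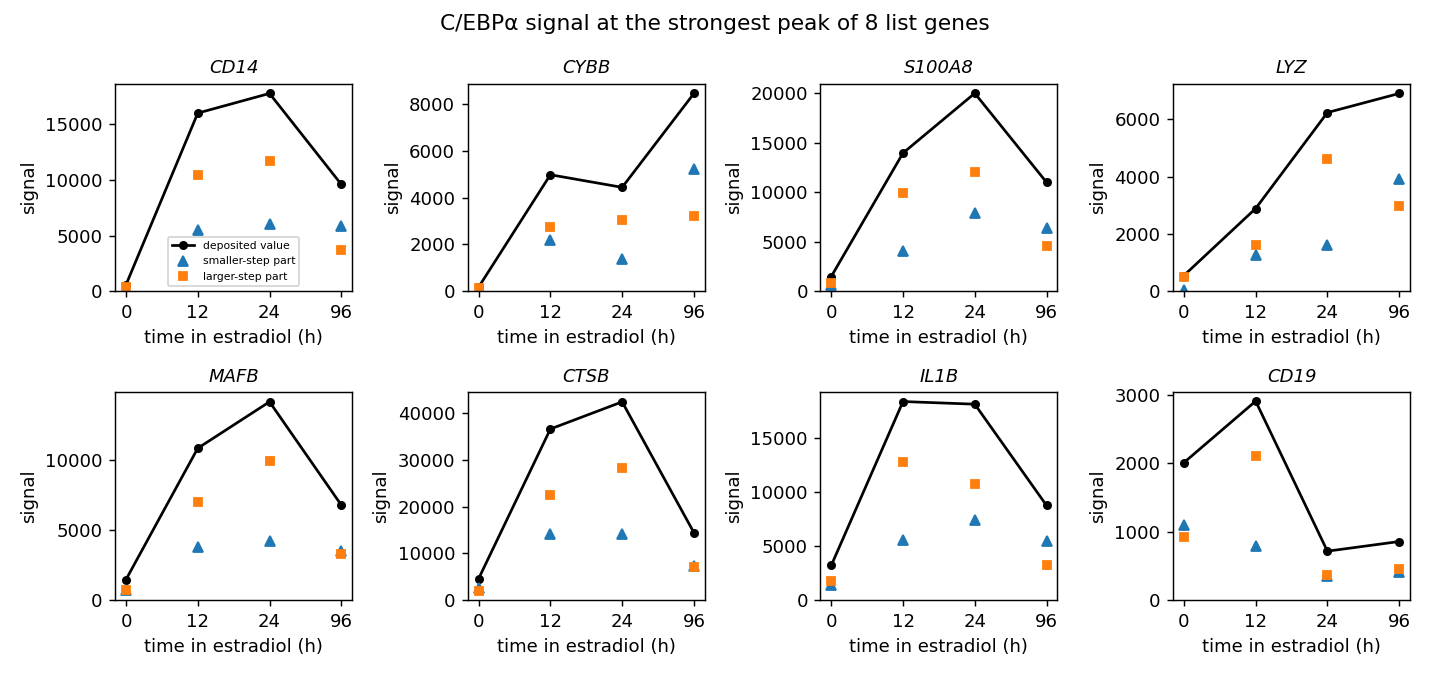
C/EBPα signal (y axis, deposited scale, each panel from 0) at the strongest peak of 8 list genes against time in estradiol (x axis, 0, 12, 24 and 96 h, spaced evenly and not to scale), with the deposited value as a black line and the 2 parts of each time as blue triangles (smaller step) and orange squares (larger step). The CD14 peak went from 606.2 at 0 h to 17767 at 24 h, and the CYBB peak reached 8428 at 96 h.

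Myeloid transcription factor genes gained binding as a list at 12 h and 24 h only at the 100 kb limit. Of 41 peaks, 16 rose at 12 h, 15 at 24 h and 9 at 96 h, and 1 fell at 96 h, while adjusted over the list alone 22, 18 and 10 rose and 1 fell at 96 h. The median log2 change was 1.69, 1.43 and 0.65 (camera, adjusted p = 0.0309, 0.0309 and 0.547). The adjusted p was 0.947 with an estimated correlation, and both calls also ended at the 20 kb limit (13 peaks, adjusted p = 0.215 at 12 h and 0.233 at 24 h). The strongest peak of RARA, the retinoic acid receptor alpha gene, rose by 3.02 ± 0.63 at 96 h (SE, chromosome 17, 40333984 to 40334396, intron, adjusted p = 4.99e-05), and that of RUNX1, a haematopoietic transcription factor, by 2.64 ± 0.59 (SE, chromosome 21, 35932263 to 35932752, intron, adjusted p = 0.000165). FOS, an AP-1 subunit, and MAFB, a monocyte and macrophage transcription factor, each rose by 2.20 at 96 h (SE 0.54 and 0.55, adjusted p = 0.000683 and 0.000908). After median-of-ratios scaling the list had 3, 9 and 8 rises and 0, 2 and 4 falls.

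Inflammatory mediator genes also gained binding as a list at 12 h and 24 h, with 16, 17 and 8 of 45 peaks higher at 12, 24 and 96 h and 2 lower at 96 h. Adjusted over the list alone, 20, 20 and 9 rose and 2 fell at 96 h. The median log2 change was 1.32, 1.47 and 1.03 (camera, adjusted p = 0.0488, 0.0305 and 0.747). The adjusted p was 0.947 with an estimated correlation, and the call at 12 h also ended after GC correction (adjusted p = 0.0509). At 96 h the promoter peak of TREM1, an activating receptor of myeloid cells, rose by 4.13 ± 0.68 (SE, chromosome 6, 41286571 to 41287091, adjusted p = 1.76e-07), a call that ended after median-of-ratios scaling at an estimate of 3.54 (adjusted p = 0.0714). The IL1RN peak, at the interleukin-1 receptor antagonist gene, rose by 2.50 ± 0.63 (SE, chromosome 2, 113127214 to 113127610, intron, adjusted p = 0.00117) and that of PTGS2, the inducible cyclooxygenase gene, by 2.07 ± 0.51 (SE, chromosome 1, 186618396 to 186618940, adjusted p = 0.000822). After median-of-ratios scaling the list had 7, 8 and 6 rises and 1, 2 and 5 falls.

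Granule genes of granulocyte precursors had 4 peaks, of which 2, 3 and 2 rose at 12, 24 and 96 h, also adjusted over the list alone. The median log2 change was 1.60, 2.60 and 1.91 (camera, adjusted p = 0.497, 0.0309 and 0.298). The adjusted p was 0.947 with an estimated correlation. CAMP, the cathelicidin gene, rose by 3.08 ± 0.63 at its promoter by 96 h (SE, chromosome 3, 48223082 to 48223507, adjusted p = 3.57e-05), and MMP8, neutrophil collagenase, by 2.71 ± 0.74 (SE, chromosome 11, 102727713 to 102728124, promoter, adjusted p = 0.00287). MPO, the myeloperoxidase gene, rose by 2.42 ± 0.59 at 24 h (SE, chromosome 17, 58284726 to 58285372, adjusted p = 0.000679) and stood at 1.11 ± 0.59 at 96 h (SE, adjusted p = 0.177).

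Genes that C/EBPα binds in liver and fat cells had 11 peaks, of which 5, 6 and 5 rose at 12, 24 and 96 h, and 5, 7 and 5 adjusted over the list alone. The median log2 change was 2.03, 2.06 and 1.49 (camera, adjusted p = 0.195, 0.00883 and 0.255). The adjusted p was 0.947 with an estimated correlation, while at the 20 kb limit the list was called at 12 h too (7 peaks, adjusted p = 0.0278). At 96 h the peak near SERPINA1, the alpha-1-antitrypsin gene, which monocytes also express, rose by 3.04 ± 0.56 (SE, chromosome 14, 94392460 to 94392981, adjusted p = 3.03e-06). HP, the haptoglobin gene, rose by 2.82 ± 0.71 (SE, chromosome 16, 72051852 to 72052219, adjusted p = 0.00109), a call that ended after median-of-ratios scaling at an estimate of 2.22 (adjusted p = 0.113).

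B cell genes were not called as a list. Of 31 peaks, 3 rose at 12 h, 4 at 24 h and 2 at 96 h, and 0 fell by limma at any of the 3 times. At an unadjusted p under 0.05, 8, 5 and 4 were higher and 0, 0 and 2 lower. Adjusted over the list alone 3, 4 and 0 rose. The median log2 change was 0.81, 0.77 and 0.26 (camera, direction down at each time, adjusted p = 0.744, 0.547 and 0.0890). After median-of-ratios scaling the medians were −0.17, −0.05 and −0.35, with 0 rises and with 0, 2 and 4 falls. CD79A, a signalling chain of the B-cell receptor, stood at −1.53 ± 0.78 at 96 h (SE, chromosome 19, 41871654 to 41871950, exon, adjusted p = 0.158), and CD19, a B-cell co-receptor, at −1.22 ± 0.77 (SE, chromosome 16, 28912585 to 28912925, intron, adjusted p = 0.266). After median-of-ratios scaling both fell, by 2.13 and 1.83 on the log2 scale (adjusted p = 0.0256 and 0.0347). CIITA, the activator of MHC class II genes, rose by 2.06 ± 0.64 at 24 h (SE, chromosome 16, 10862419 to 10862862, adjusted p = 0.0101) and stood at 1.36 ± 0.64 at 96 h (SE, adjusted p = 0.118).

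The other lists were not called at any time. Phagosome and lysosome genes had 15 peaks with 4, 4 and 5 rises at 12, 24 and 96 h, the same counts adjusted over the list alone, and a camera adjusted p of 0.497, 0.598 and 0.692. Their median at 96 h was 0.06, and −0.54 after median-of-ratios scaling, although the direction by camera was up. CTSB, the cathepsin B gene, rose at 96 h by 1.67 ± 0.48 (SE, chromosome 8, 11858430 to 11859233, intron, adjusted p = 0.00538), and LAMP1, a lysosomal membrane protein gene, by 2.81 ± 0.65 (SE, chromosome 13, 113299897 to 113300310, intron, adjusted p = 0.000339). Lipid and cholesterol handling genes had 19 peaks with 7, 6 and 2 rises and 2 falls at 96 h, with the same counts adjusted over the list alone (camera, adjusted p = 0.598, 0.765 and 0.598). The peak upstream of ABCA1, a cholesterol exporter, rose by 3.13 ± 0.53 at 96 h (SE, chromosome 9, 105006994 to 105007527, adjusted p = 4.32e-07), and that of LDLR, the LDL receptor gene, stood at −1.29 ± 0.56 (SE, chromosome 19, 11074282 to 11074974, adjusted p = 0.0823).

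T cell and NK cell genes had 11 peaks with 0, 0 and 2 rises by limma, the same counts adjusted over the list alone, and 1, 4 and 2 higher at an unadjusted p under 0.05 (camera, adjusted p = 0.875, 0.777 and 0.819). GNLY, the granulysin gene, rose by 1.87 ± 0.62 at 96 h (SE, adjusted p = 0.0168) and NCAM1, an adhesion molecule of NK cells, by 1.82 ± 0.67 (SE, adjusted p = 0.0362), and both calls ended after median-of-ratios scaling at estimates of 1.27 and 1.22 (adjusted p = 0.0533 and 0.120). Cell cycle and housekeeping genes had 11 peaks with 4, 3 and 3 rises, also adjusted over the list alone (camera, adjusted p = 0.869, 0.773 and 0.777), and a median at 96 h of −0.06, or −0.66 with 4 falls after median-of-ratios scaling. MKI67, a marker of dividing cells, rose by 1.40 ± 0.50 at 96 h (SE, adjusted p = 0.0314), and MYC, a growth regulator, stood at −1.29 ± 0.64 (SE, adjusted p = 0.141) and fell by 1.89 after median-of-ratios scaling (adjusted p = 0.00520). The CTSD and GAPDH peaks, at the cathepsin D gene and a glycolytic gene, had no parts to test and deposited log2 changes of 2.18 and −1.92 at 96 h. Erythroid and megakaryocyte genes had 2 peaks, too few for camera. That of TAL1, a haematopoietic transcription factor, rose by 1.75 ± 0.67 at 12 h (SE, adjusted p = 0.0466, and an estimate of 0.76 with an adjusted p of 0.351 after median-of-ratios scaling), and that of PF4, platelet factor 4, stood at −0.47 ± 0.95 at 12 h (SE, adjusted p = 0.749).

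**Figure D2:**
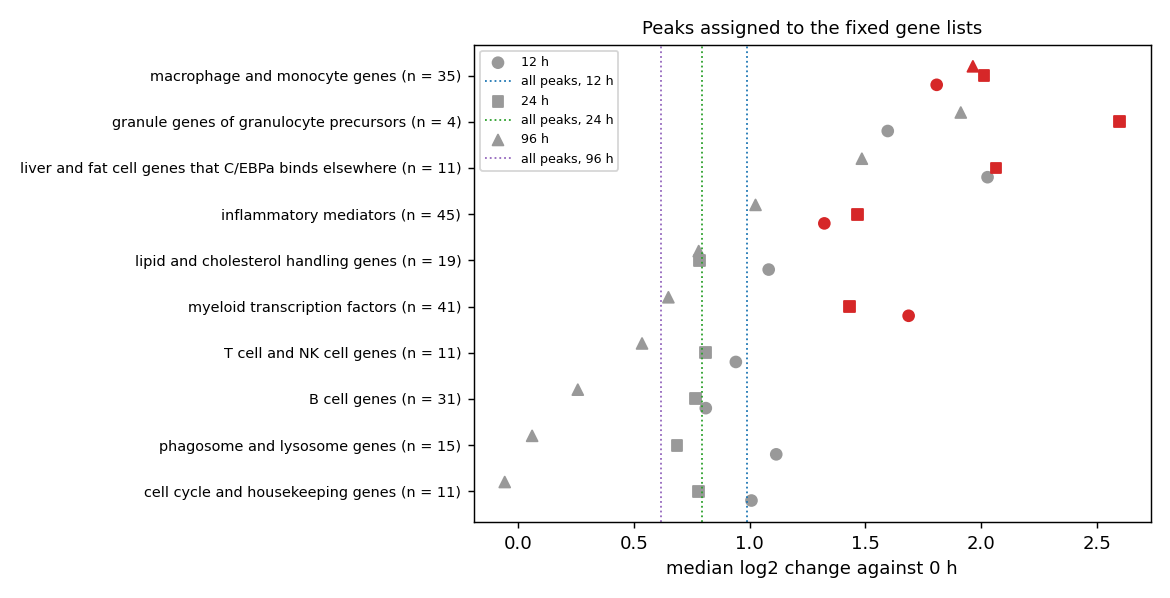
Median log2 change against 0 h (x axis) of the peaks assigned to 10 gene lists (y axis) at 12, 24 and 96 h, with dotted lines at the median of all tested peaks at each time. Red symbols mark the 9 list and time pairs with an adjusted p under 0.05 by camera at the preset correlation. None of them was called by camera with a correlation estimated on the unscaled parts (lowest adjusted p = 0.947), into which level differences between parts enter. The macrophage and monocyte list had medians of 1.81, 2.01 and 1.96.

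Most C/EBPα peaks lay away from promoters. By the midpoint of the peak 51.1% were intergenic, 42.0% intronic, 4.00% exonic and 2.99% within 1 kb of a transcription start (436 peaks, 95% Wilson interval 2.73 to 3.28%). Peaks of the lost class were in promoters more often than peaks in no class, at 8.08% against 2.84% (Fisher's exact test, two-sided, adjusted p = 2.99e-06 over 7 tests), and late peaks less often, at 1.21% (adjusted p = 0.00853). With classes made after median-of-ratios scaling the late call ended (1.62% against 2.50%, Fisher's exact test, adjusted p = 0.115). Early peaks, at 2.99%, were not told apart from peaks in no class within 1 kb (adjusted p = 0.699), but within 5 kb they were, at 10.4% against 8.96% (Fisher's exact test, adjusted p = 0.0259). Peaks are not independent replicates, and these intervals and tests cover counting error only.

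C/EBP sites were the most common of 6 sequence sites searched in the central 200 bp, found in 55.8% of peaks against 17.4% of windows 2 kb away. Sites for PU.1, the myeloid and B-cell ETS factor, were found in 5.36% against 0.879%, for AP-1 in 7.86% against 3.21%, for RUNX factors in 23.1% against 14.3% and for EBF, a B-cell factor, in 0.996% against 0.268%. The E-box of E2A, another B-cell factor, was found in 12.4% of peaks and 17.9% of the windows 2 kb away. The strings matched were TKNNGYAAK for C/EBP, GAGGAAGT for PU.1, TGASTCA for AP-1, TGTGGT for RUNX, TCCCNNGGGA for EBF and CAGGTG for E2A. They differ in length and in the bases they allow, so shares of different sites cannot be ranked as frequencies of the factors' sites.

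Each timing class was compared with peaks in no class, and not with the other classes, for its sequence sites. Early peaks held PU.1 sites in 9.45% against 3.79% of peaks in no class (Fisher's exact test, adjusted p = 2.77e-27 over 36 tests), AP-1 sites in 12.8% against 6.41% (adjusted p = 1.66e-24) and RUNX sites in 29.4% against 21.6% (adjusted p = 5.74e-16). In this window E2A sites were fewer in early peaks (8.17% against 13.7%, adjusted p = 4.84e-15), but over whole peaks the difference ended (23.7% against 24.1%, Fisher's exact test, adjusted p = 0.725). Late peaks held E2A sites in 5.27% (adjusted p = 1.36e-14) and PU.1 sites in 9.99% (adjusted p = 1.09e-13). C/EBP sites were found in 60.9% of early and 66.9% of lost peaks against 54.3% (Fisher's exact test, adjusted p = 2.75e-09 and 2.64e-06). Lost peaks held EBF sites in 4.04% against 0.961% (adjusted p = 1.71e-05), E2A sites in 21.5% and PU.1 sites in 1.52% against 3.79% (adjusted p = 0.0238 for PU.1). In the central 100 bp lost peaks held PU.1 sites in 0.505% against 2.07% (Fisher's exact test, adjusted p = 0.0521). Transient peaks held EBF sites in 3.70% and RUNX sites in 35.0% (adjusted p = 1.02e-05 for RUNX). They held AP-1 sites in 14.4% against 6.41% (Fisher's exact test, adjusted p = 3.18e-05), a call that ended in the central 100 bp (4.53% against 3.29%, adjusted p = 0.365). GC content was not alike either, with medians of 51.5% in lost, 41.0% in late and 45.0% in peaks in no class, and the site and promoter shares were not adjusted for it. Chromosome 8 was kept in, and 38.8% of its peaks held a C/EBP site against 59.3% on the other autosomes. A fit without it called 2693 of 11090 peaks higher at 12 h, against 2814 of 13288 with it. Its peaks among those in no class may thus widen the C/EBP differences, and no site or promoter test was run without it. With classes made after median-of-ratios scaling, lost peaks held EBF sites in 3.20% against 0.825% (adjusted p = 7.01e-10). Other calls changed with those classes. Late peaks then held C/EBP sites in 63.1% against 54.1% (Fisher's exact test, adjusted p = 6.50e-08, and 0.355 in the main classes). Lost peaks then held AP-1 sites in 4.56% against 7.44% (Fisher's exact test, adjusted p = 0.000208, and 0.398 in the main classes).

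**Figure D3:**
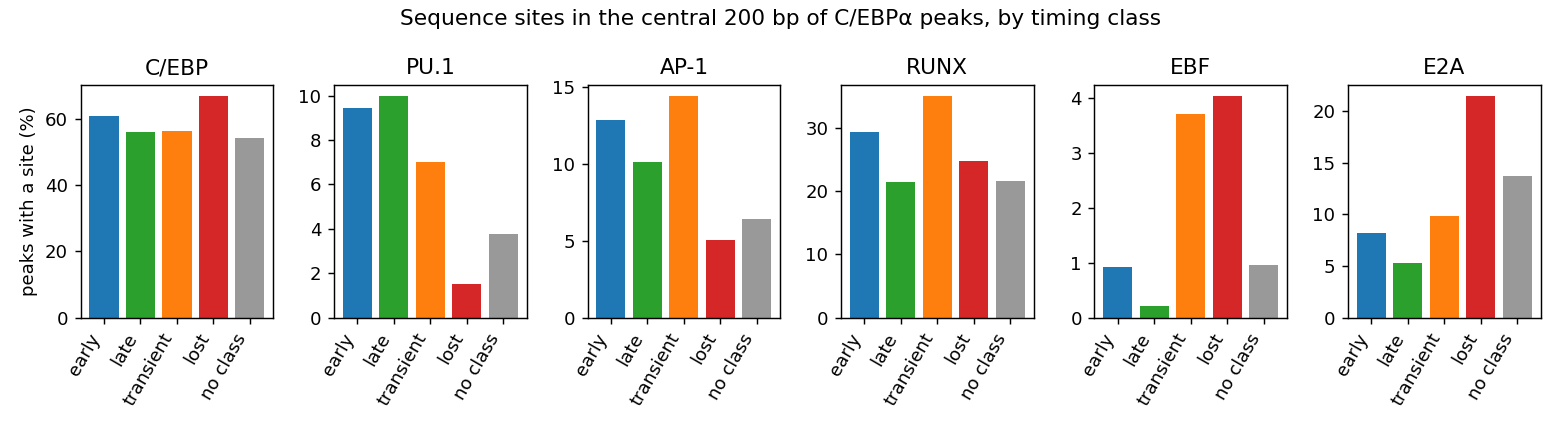
Percent of C/EBPα peaks (y axis, from 0, own scale per panel) with a match to each of 6 sequence sites in the central 200 bp, for the early, late, transient and lost classes and for peaks in no class (x axis). PU.1 sites were found in 9.45% of early and 9.99% of late peaks against 3.79% of peaks in no class, and EBF sites in 4.04% of lost peaks against 0.961%.

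Chromosome 8 held 2392 of the peaks, or 16.5 per Mb against 4.32 per Mb on the other autosomes. A C/EBP site was found in 38.8% of its peaks against 59.3% elsewhere, and its median log2 change at 12 h was 0.28 against 1.11. Among the other autosomes the site share was lowest on chromosomes 21 and 18 (44.3% and 49.1%), with median changes of 1.18 and 0.48. The CTSB, MYC, PAG1, PTK2B and UBXN2B peaks named above lie on it.

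**Figure D4:**
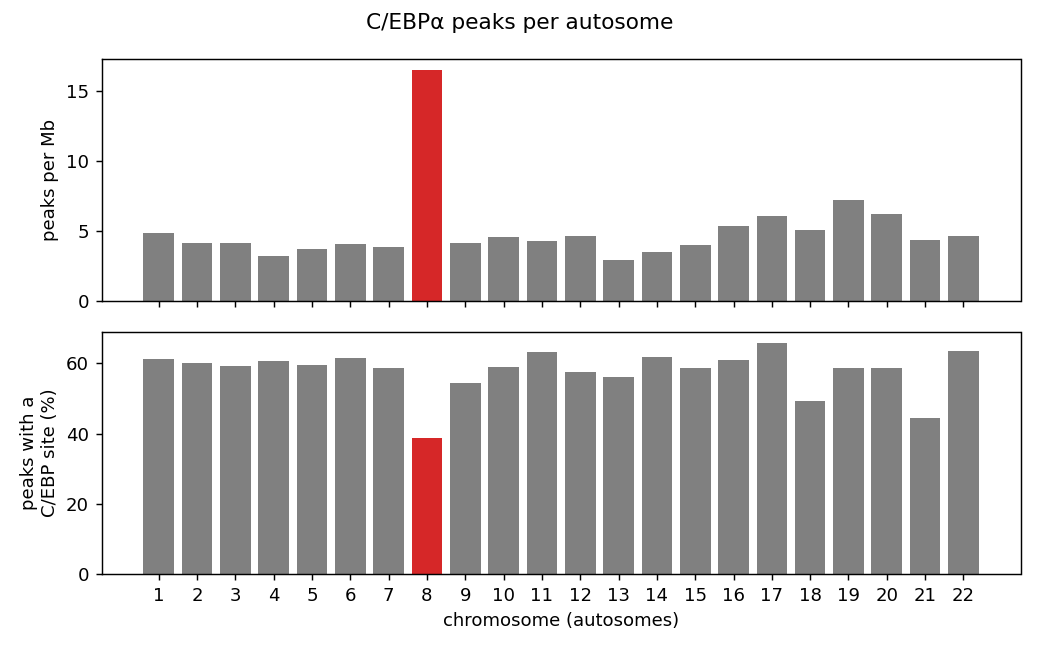
Peaks per Mb (upper panel) and percent of peaks with a C/EBP site in the central 200 bp (lower panel) on each autosome (x axis), with chromosome 8 in red and the others in grey. Chromosome 8 had 16.5 peaks per Mb and a site share of 38.8%, against 4.32 per Mb and 59.3% over the other autosomes.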

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

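All tests in this part were chosen after the results were seen. The K0 and A0 marks of the peak list entered none of the comparisons of binding over time, and no source says what they stand for, so their values are given without an explanation. K0 was TRUE for 5458 peaks (37.5%) and A0 for 5181 (35.6%), with 3511 TRUE for both and 7433 for neither. Peaks with K0 rose at 12 h more often than peaks without it, at 29.3% against 16.2% of tested peaks (limma calls, Fisher's exact test, adjusted p = 1.57e-69 over 8 tests), and so did peaks with A0, at 30.1% against 16.2% (adjusted p = 1.53e-75). At 96 h peaks with A0 rose less often than peaks without it, at 13.0% against 19.2% (adjusted p = 2.52e-20), and fell more often, at 5.87% against 1.37% (adjusted p = 1.11e-45). K0 went the same way at 96 h, with rises in 15.6% against 17.9% and falls in 4.21% against 2.24% (Fisher's exact test, adjusted p = 0.000464 and 2.26e-10). The marks overlap, and at 96 h peaks with K0 alone rose in 18.9%, peaks with both in 13.7% and peaks with neither in 19.3%. The K0 difference in rises thus lay in peaks that also had A0. Falls were found in 2.99% of peaks with K0 alone and 0.946% of peaks with neither. Of peaks with A0 alone 13.4% lay in promoters, against 1.41% of peaks with neither. Median deposited values at 0 h were 1337 with K0, 1399 with A0 and 1063 with neither, so the groups also differed in signal before estradiol.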

How the results depend on the processing

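Settings added after the data were seen were the test on parts, leaving out chromosome 8 or, for the 2-fold counts, peaks below 10 Mb, the GC correction, the list tests after scaling or GC correction and 96 h as the last time. The others were planned, for libraries and not for parts. Of counts and shares, 183 alternatives stayed within 1.5 times the main count or within the interval of the share and 95 moved. Of alternatives for list tests, 104 gave the same outcome as the main run, 12 lost a call and 1 gained one. The main run called only 9 of 30 list and time pairs, so most of the 104 were pairs called in neither run. The correlation estimated on unscaled parts called 0 of 30 pairs and the 20 kb limit 8 of 27. Median-of-ratios scaling called 9 of 30 and GC correction 8 of 30. All 200 alternatives for named peaks kept their direction, but they covered only the 5 largest rises and 5 largest falls per comparison. These peaks were picked for their size, and median-of-ratios scaling removed a median log2 change of 1.02 or less, so a reversal was hardly possible. Peaks named from the gene lists were not among them, and some of their calls ended after that scaling, as at TREM1 and HP.

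Counts of peaks at least 2-fold higher and lower, as deposited 7370 and 296 at 12 h, 6350 and 610 at 24 h and 5397 and 1401 at 96 h against 0 h, were 2192 and 2330, 2801 and 2709, and 3235 and 2850 after median-of-ratios scaling, and 2168 and 2349, 2656 and 2908, and 2737 and 3390 after scaling to column totals. In peaks above the median mean signal, which are fewer by construction, they were 4332 and 17, 3668 and 184, and 2853 and 591. From 12 h to 24 h the lower count was 1425 after median-of-ratios scaling (2215 as deposited), with 215 higher and 735 lower in the stronger peaks. From 24 h to 96 h the stronger peaks gave 527 higher and 1641 lower, and leaving out chromosome 8 gave 1181 higher (1799 with it).

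By limma on the parts, rises and falls at 12 h (2814 and 12) were 786 and 304 after median-of-ratios scaling and 790 and 302 after scaling to totals. At 24 h (2696 and 52) they were 1332 and 852, and 1305 and 897, with 106 falls when only the 2 times were fitted. At 96 h (2262 and 396) falls were 1250 after median-of-ratios scaling, and rises and falls 1341 and 1524 after scaling to totals. In the stronger peaks 0 fell at 12 h (limma, 3098 with an unadjusted p under 0.05) and 232 at 96 h. From 12 h to 24 h (0 and 0) there was 1 rise under either scaling and 1 fall at a pseudocount of 10. From 24 h to 96 h (269 and 515) there were 775 rises after median-of-ratios scaling, 663 rises and 877 falls after scaling to totals, 51 and 336 in the stronger peaks, 94 rises after GC correction, 131 without chromosome 8, and 518 rises and 434 falls when only the 2 times were fitted. Either scaling took out a shift common to the peaks, with a median log2 change at 12 h of 0.99 as deposited, 0.007 after median-of-ratios scaling and 0.010 after scaling to totals. This lowers the rises and raises the falls against 0 h. Apart from this and the smaller peak sets, the cause of the shifts was not tested.

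Leaving out 1 part at a time, with the lone part assumed to vary like the other times, gave 523 to 3088 rises and 0 to 17 falls at 12 h, 822 to 2672 and 3 to 77 at 24 h, 1094 to 2365 and 132 to 402 at 96 h, 0 rises and 0 to 80 falls from 12 h to 24 h, and 30 to 312 and 120 to 454 from 24 h to 96 h. Over all times 2586 to 4326 peaks changed, the lowest number without the smaller-step 0 h part. Parts exist only for the limma results.

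The early class held 786 peaks after median-of-ratios scaling, 790 after scaling to totals and 1567 at an adjusted p under 0.01 (2814 otherwise). The lost class held 1250, 1524 and 176 (396 otherwise) and the transient class 66 at the stricter threshold (243 otherwise). With a correlation estimated on unscaled parts, camera called 0 list and time pairs, with 0 at an unadjusted p under 0.05 (9 called at the preset one, with 10 at an unadjusted p under 0.05). Promoter peaks were 9.48% within 5 kb. Sites in the central 100 bp and in whole peaks were 41.9% and 66.7% for C/EBP, 2.97% and 7.51% for PU.1, 3.96% and 12.5% for AP-1, 12.3% and 35.0% for RUNX, 0.494% and 1.79% for EBF and 5.82% and 24.0% for E2A, as the width searched changes.

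No paired analysis was possible because the columns carry no replicate numbers. A count test with DESeq2, all comparisons of the later time and overlaps of peak lists per time were not run, as the values are not counts and the files used here hold 1 merged list. Read depth is unknown, so limits set by depth could not be given.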

Other observations

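All tests in this part were chosen after the results were seen, except the test of the last 10 Mb of chromosomes and the comparison of GC slopes. Sites of EBF, RUNX, E2A and AP-1 were more frequent in the peaks that fell from 24 h to 96 h, which were also richer in G and C (median 50.0% against 44.5%). EBF sites were found in 4.85% of these peaks against 0.848% of peaks not called between the times (Fisher's exact test, adjusted p = 2.35e-10), RUNX sites in 31.3% against 23.2%, and E2A sites in 16.3% against 12.2% (adjusted p = 0.0136). AP-1 sites were found in 11.5% against 7.92% (Fisher's exact test, adjusted p = 0.0117), a call that ended in the central 100 bp (4.85% against 4.04%, adjusted p = 0.434). Peaks that rose held E2A sites in 4.46% (adjusted p = 7.03e-05) and RUNX sites in 13.8%, a RUNX difference that ended in the central 100 bp (8.92% against 12.4%, Fisher's exact test, adjusted p = 0.143). ADIPOQ, the adiponectin gene, had a peak that rose by 2.40 ± 0.53 at 12 h (SE, limma, adjusted p = 0.000185) and stood at −0.27 ± 0.53 at 96 h (SE, adjusted p = 0.768), with −2.25 ± 0.53 from 24 h to 96 h (SE, adjusted p = 0.00225). The IL1B peak rose by 2.40 ± 0.51 and 1.41 ± 0.51 at the same times (SE, adjusted p = 0.000101 and 0.0345). Both were chosen after their values were seen, and 96 h was not tested against 12 h.

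Chromosome 8 held 16.5 peaks per Mb against 4.32 on the other autosomes. A few dense clusters are argued against, since 27 of its 29 windows of 5 Mb (93.1%) held more peaks than the 90th percentile of windows elsewhere (40 peaks). Its share of peaks with a C/EBP site was lower by −20.6 percentage points, as background peaks that passed the peak threshold would give. A site was held by 927 of its peaks, where 701.7 would follow from the density elsewhere plus background (ratio 1.32, 95% interval 1.24 to 1.41). That number takes background peaks to hold sites as often as its windows 2 kb away (18.7%), which was not tested. The interval covers counting error only, so background alone is argued against only if that share holds. Extra copies of the chromosome in this line are a possible explanation of both more background and more sites, which was not tested, as no input values were used here. No biological explanation from the design was tested.

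Signal was lower for peaks that start in the first 10 Mb of a chromosome, with a step in the median log2 value at 10 Mb of 1.19, 0.83, 1.14 and 0.91 at 0, 12, 24 and 96 h between the adjoining windows of 1 Mb. A decline of binding towards chromosome ends is argued against, since the last 10 Mb differed from the 10 Mb before by a log2 of 0.0920 (95% interval 0.02 to 0.17) at 0 h. Processing by position is a candidate explanation, since 0% of the peaks below 10 Mb had parts at all 4 times. What that processing was stays open, and levels of CD163, CTSD, GAPDH and other peaks below 10 Mb should not be set beside levels elsewhere. Because the step was not the same at each time, changes of such peaks over time may be shifted too. This holds also for RFLNB, RHBDF1, TUBB8B and THOC1. No biological explanation from the design was tested.

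Peaks that fell from 24 h to 96 h were richer in G and C (median 50.0%) than peaks that rose (37.5%). A GC bias of the libraries was taken to give alike slopes in groups of peaks made by marks and sites, and the slope of the log2 change per 10 GC points was −0.83 in peaks with neither K0 nor A0 and no C/EBP site and −0.47 in peaks with both marks and a site (ratio 1.78, 95% interval 1.46 to 2.20), which met neither bound set beforehand. After the GC trend of each part was removed, 364 of the 784 calls (46.4%) remained, with 79 rises and 285 falls. This lay between the bounds for a trend that makes nearly all calls and one that makes few, so a GC bias and a change in binding cannot be told apart for the others. The GC slopes between parts of 1 time (−0.35 at 24 h and 0.24 at 96 h) stood beside slopes between the times of −0.44 to −1.03 by pair of parts (−0.73 together), and a loss of binding at GC-rich sites over time stays open for the calls that ended.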
